A study of Mus musculus with 4 samples.

How the data were processed

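Egr2 ChIP-seq was analysed in 2 mouse libraries, 1 from NKT cells of Va14tg mice and 1 from thymocytes of mice injected with an antibody against TCRβ. Per the labels' protocols, 100 ng of ChIP DNA was used per library, libraries were amplified with 16 PCR cycles, fragments of 150 to 400 bp were selected on a gel, and sequencing was done on an Illumina GAII instrument. Reads were aligned with Bowtie to mm9, per the submitters' processing notes; the Bowtie version was not given in the sources used here. The labels give the strain Va14tg to all 4 libraries of the series, and the input DNA and IgG libraries were not analysed here. Which of them served as control for which list was not given in the sources used here.

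The authors deposited 1 peak list per Egr2 library. Each list pairs region lines with peak lines and names its values within each line. This layout, with strand shift, strand correlation and a rank by q value, is that of the QuEST peak caller, but the caller and its settings were not given in the sources used here. The signal values in the deposited lists are a ChIP tag density and a control tag density at the summit, whose scaling is not stated. The ChIP densities are whole multiples of a step, which rounds to 0.0822 in injected thymocytes and 0.0866 in NKT cells. This does not hold for the control densities. The fold over control in the deposited lists is the ratio of the ChIP density to the control density, or to 1 where the control density is lower, which the values follow to within 7.42e-05. The lowest values in the lists, a ChIP density near 10 and a fold near 2.50, show that both were limited from below. The regions also carry deposited whole numbers of ChIP and control tags, and a tag enrichment. In regions with more than 50 control tags this enrichment equals the ratio of ChIP to control tags times 1 factor per list, 0.742 in injected thymocytes and 1.14 in NKT cells. These regions number 7 and 17. Tag ratios were scaled by these factors, and that the factors reflect library depth is an assumption, since depths were not given. In regions with 1 to 10 control tags the deposited enrichment was lower than the ratio obtained in this way by more than 1% in 1842 of 3434 injected-thymocyte regions and in 845 of 1860 NKT regions, and higher by more than 1% in none. All densities and folds are the authors' values for each peak, and they were used to describe and rank peaks within a list. Across the lists they were used for the correlation over shared pairs and for the share expected at the density limit of the NKT list. Neither changes with a constant scale factor between the lists, whereas a ratio of densities between the lists would, and none is given.

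Regions are numbered in the order of falling density. Numbers run to 4975 in injected thymocytes and 2885 in NKT cells, and 760 and 890 of them (15.3% and 30.8%) are absent from the lists as analysed here, among them those before number 9 and number 44. Peaks under these numbers were not analysed here, and the highest ranks below refer to the lists as analysed. The 10 tallest listed peaks carry numbers 9 to 19 in injected thymocytes and 44 to 86 in NKT cells. The top groups of the NKT list thus lack many of the highest regions, and more than those of injected thymocytes. Coordinates are mm9 as the lists give them, and whether the lists count from 0 or from 1 was not given in the sources used here.

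Before the data were examined, the overlap criteria, the random placements, the alternatives, the rule for named items and 13 gene lists were fixed. The gene table at hand was of GRCm38, another build than the lists, and no mm9 genome or annotation was used here. Coordinates were not converted between builds. The planned assignment of peaks to genes, the gene lists, the location relative to transcription starts and the search for the EGR motif were therefore not run, and positions are given in place of gene names. Items were named by the parts of the rule that need no gene: the 10 tallest peaks of each list, the 5 tallest peaks of each list that did not overlap the other, and the 5 shared peaks with the best sum of ranks.

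Peaks were called shared when their regions overlapped by at least 1 bp. No regions overlapped within a list. Chance overlap was described by 1000 random placements of each NKT peak between the first and last peak on its chromosome. Shares carry 95% exact (Clopper-Pearson) binomial intervals. Tag ratios carry the exact interval of a ratio of 2 counts, and where no control tag was counted the ratio is a lower bound against 3 tags per region. That bound rests on the counts alone, and the deposited enrichment can lie below it. Intervals of medians come from 2000 bootstrap draws over peaks. All of these cover counting error only, and they treat tags and peaks as independent. PCR duplicates are not independent molecules, so the intervals may be too narrow where duplicates were counted. With 1 library per condition no p-value between conditions was computed. Alternatives were a reciprocal overlap of 50%, summits within 100 bp, regions extended by 500 bp, the upper 50% of each list, equal numbers of peaks, other rankings and other numbers of top peaks. Restrictions to peaks with a strand shift of 60 bp or more, or with a control density under 3, were added after seeing the data.

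The overlap count was tested on 20 simulated pairs of lists with the sizes and widths of the real lists and 300 planted shared regions. All 300 were found in every pair, the counts ran from 300 to 302, and random placement gave a mean of 1.20. The planted regions were centred close enough to overlap by construction. This tested the counting, and not how well the 1 bp rule finds shared binding. Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures Matplotlib 3.10.9.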

Results

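Egr2 occupancy was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in mouse natural killer T (NKT) cells and thymocytes. Egr2 (Krox-20) is a zinc-finger transcription factor that T cells induce when their antigen receptor (TCR) is engaged. One library came from NKT cells, a T cell lineage that recognises lipids presented by CD1d, purified from Va14tg mice with CD1d tetramers; about 10 mice were pooled per experiment. The other Egr2 library came from thymocytes of mice given 500 µg of an antibody against TCRβ, which delivers a strong receptor signal in vivo, and collected 24 hours later from 3 to 5 mice. Each preparation used 20000000 cells. The series also lists an input DNA library and an IgG control ChIP. Peak lists of the 2 Egr2 libraries were analysed here, with 1 library per condition, so no difference between the conditions has a replicate check, and the intervals given below cover counting error only.

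The injected-thymocyte list held 4216 peaks and the NKT list 1996, each peak in a region of its own, on the 19 autosomes and the X chromosome. The regions were narrow: the median width was 155 bp in injected thymocytes and 142 bp in NKT cells, and they covered 850866 bp and 358868 bp of the mm9 genome. Most peaks lay just above the lowest listed height. The ChIP tag density, the authors' own height value for each peak, started at 10.0 in injected thymocytes and 9.96 in NKT cells, and its medians were 11.2 and 11.1. The highest density was 97.0 in injected thymocytes and 93.5 in NKT cells. The smallest enrichment over the control density was 2.50-fold in both lists, and the medians were 10.5-fold and 10.2-fold. A median region rested on 16 ChIP tags and 2 control tags in injected thymocytes and on 15 ChIP tags and 4 control tags in NKT cells. In 700 injected-thymocyte regions and 75 NKT regions no control tag was counted. Total library depths were not given in the sources used here, and the precision of each region is set by its own tag counts.

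**Figure D1:**
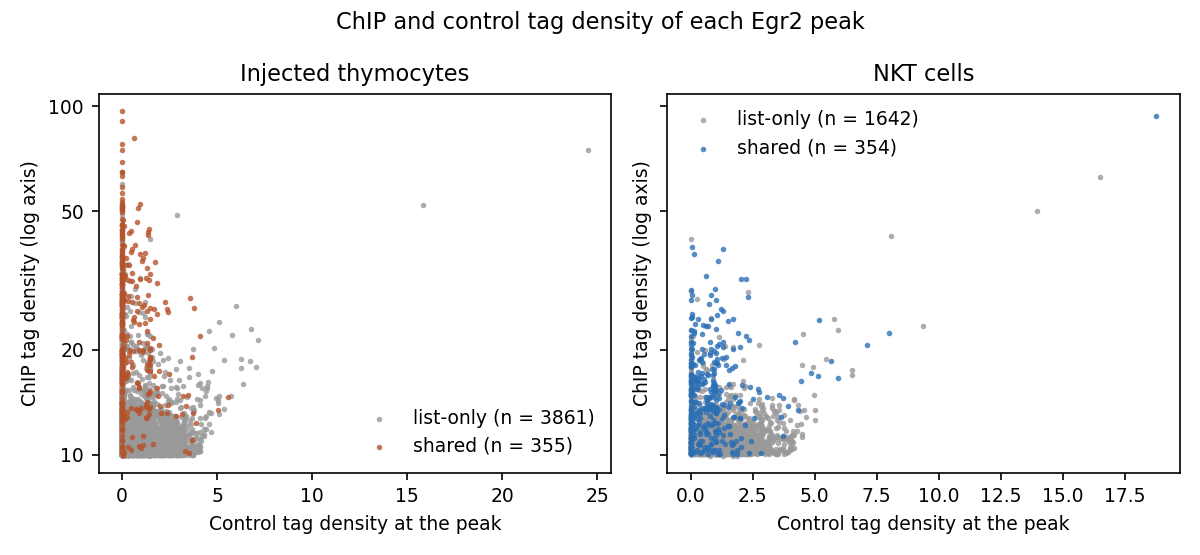
Each point is one Egr2 peak, with the control tag density at the peak on the horizontal axis and the ChIP tag density on a logarithmic vertical axis, in injected thymocytes (left) and NKT cells (right). Coloured points overlap a peak of the other list and grey points do not. Control densities of 5 or more occur at 1 of the 10 highest injected-thymocyte peaks, which has the highest control density of either list (24.5), and at 4 of the 10 highest NKT peaks.

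The first comparison asked how far Egr2 occupied the same positions in developing NKT cells and in thymocytes that had received a strong TCR signal. Of the 1996 NKT peaks, 354 overlapped an injected-thymocyte peak by at least 1 bp, a share of 17.7% (95% exact binomial interval 16.1% to 19.5%). Seen from the other side, 355 of the 4216 injected-thymocyte peaks were shared, or 8.42% (7.60% to 9.30%). The shared positions coincided closely: the 2 summits lay a median of 32 bp apart (quartiles 16 and 52.8 bp), and 326 of 354 pairs had summits within 100 bp. In 1000 random placements of the NKT peaks on their own chromosomes a mean of 1.29 peaks overlapped, with a highest value of 7. Shifting each NKT peak by 20 to 200 kb, which keeps it in its own neighbourhood, gave a mean of 3.10 and a highest value of 9. The remaining 1642 NKT peaks and 3861 injected-thymocyte peaks were found in 1 list only.

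Sharing was concentrated among the tallest peaks. Peaks were divided into 4 quartile groups by density within each list. In the top quartile of the NKT list, 242 of 499 peaks were shared (48.5%, interval 44.0% to 53.0%), against 11.02%, 5.81% and 5.61% in the following quartiles. In the top quartile of the injected-thymocyte list 314 of 1054 peaks were shared (29.8%, 27.04% to 32.7%), against 1.99%, 1.04% and 0.854% below it. The top quartile thus held 88.5% of the shared peaks of injected thymocytes and 68.4% of those of NKT cells. In every quartile of both lists the overlap was above the highest of 1000 random placements. The weakest quartile of the injected-thymocyte list had 9 shared peaks, against at most 3 by random placement, and the weakest NKT quartile had 28, also against at most 3. Shared injected-thymocyte peaks had a median density of 22.0 and a median enrichment of 19.97-fold, and list-only peaks of 11.02 and 10.4-fold. In NKT cells the shared peaks had medians of 14.2 and 12.9-fold, and the list-only peaks of 10.9 and 10.0-fold.

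**Figure D2:**
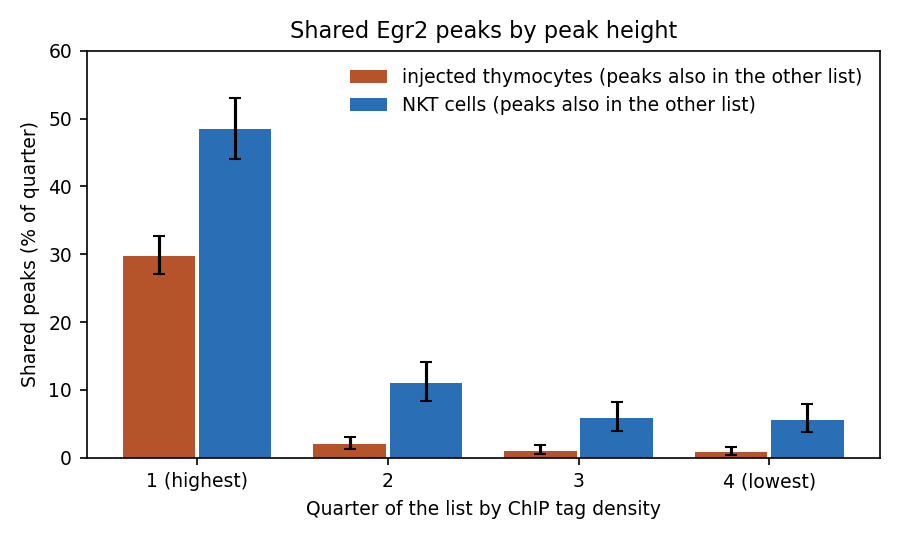
Share of peaks that overlap a peak of the other list, in percent of each quartile, for the 4 quartile groups of each list from the highest to the lowest ChIP tag density. Bars start at 0 and error bars are 95% exact binomial intervals, which cover counting error only. The top quartile reaches 29.8% in injected thymocytes and 48.5% in NKT cells, and the lower quartiles stay at or below 11.02%.

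The tallest peaks of each list were also compared with the whole of the other list, which holds 1996 peaks in 1 case and 4216 in the other. Among the top 500 peaks, 236 of injected thymocytes (47.2%, interval 42.8% to 51.7%) and 243 of NKT cells (48.6%, 44.1% to 53.1%) overlapped any peak of the other list. Of the 500 NKT peaks, 179 (35.8%, 31.6% to 40.2%) overlapped a top 500 peak of injected thymocytes. Among the top 100 peaks the shares were 72.0% and 74.0%, and 28 peaks were in the top 100 of both lists. Across the 354 shared pairs the densities in the 2 lists were weakly related (Pearson r = 0.34 on log density, Spearman rho = 0.35). This relation is across peaks of 1 library each, and peaks are not independent replicates. Both densities were limited from below near 10, and 7 of the shared NKT peaks had a control density of 5 or more. The effect of either on the relation was not tested.

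The positions that ranked highest in both lists were named first. The best combined rank belonged to chr1:137029077-137029512 in injected thymocytes, which had a density of 81.0 and 171 ChIP tags against 1 control tag. The NKT peak there, at chr1:137029055-137029432, had a density of 39.1, and its ChIP tags exceeded the control tags 31.04-fold after scaling by the factor of the list (82 against 3 tags, exact interval 10.3 to 154), while the deposited tag enrichment is 18.8. The second position was chr12:117643387-117643861, with a density of 63.1 in injected thymocytes and 39.6 in NKT cells. The third was chr17:28134206-28134660, with 46.5 and 37.7. The fourth was chr8:87437078-87437469, with 77.9 and 23.7, and the fifth was chr7:135110626-135111210, with 75.1 and 23.6. At these positions the summits of the 2 lists lay at most 40 bp apart.

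In injected thymocytes, 9 of the 10 tallest peaks were shared with NKT cells. The tallest of all was chr3:153575771-153576264, with a density of 97.0 and 173 ChIP tags. No control tag was counted there. Against a floor of 3 control tags the ChIP tags were 42.8-fold higher after scaling, a bound from the counts alone. The deposited tag enrichment is lower, at 28.8. It was followed by chr6:90319236-90319644, with a density of 90.4 and 174 ChIP tags, again without a control tag. Besides the positions on chromosomes 1, 7, 8 and 12 named above, the shared peaks among the 10 tallest were chr1:24685155-24685517 at 69.4, chr5:99681797-99682307 at 64.8 and chr7:80751638-80752091 at 64.6. The remaining peak of the 10, chr11:3030672-3038880, was found in the injected-thymocyte list only. It was 8209 bp wide, its control density was 24.5, and its 3048 ChIP tags stood only 1.62-fold (1.52 to 1.73) above 1396 control tags.

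Several tall peaks of injected thymocytes overlapped no listed NKT region. Apart from the wide chromosome 11 region, the highest were chr15:8118818-8119223 with a density of 59.7 and 113 ChIP tags, chr5:147072452-147073008 with 52.1, chr4:135637590-135638108 with 52.0 and 138 ChIP tags, and chr17:23814313-23814595 with 50.3 and 75 ChIP tags. The peaks on chromosomes 15 and 17 had no control tag and the one on chromosome 4 had 1. The peak on chromosome 5 had a control density of 15.9, and its tags were 3.05-fold (2.17 to 4.39) above the control. In all, 28 of the 100 tallest injected-thymocyte peaks were absent from the NKT list. Absence from a list means that no region listed there overlapped the position. The 890 region numbers absent from the NKT list may include regions at such positions. The NKT tag count at such a position was not analysed here.

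In NKT cells, 6 of the 10 tallest listed peaks were shared, and the control signal was high under 4 of the 10. These 10 carry region numbers 44 to 86, and most of the regions numbered up to 86 are absent from the list as analysed. The tallest, chr6:124834746-124837706, had a density of 93.5 over a control density of 18.8 and was shared. Its 659 ChIP tags were fewer than its 975 control tags, a ratio of 0.768 after scaling (0.694 to 0.848). The tallest NKT-only peaks were chr11:3003335-3004809 at 62.7, chr12:48934855-48935126 at 49.98 and chr11:51269033-51269318 at 42.4, and their control densities were 16.5, 14.0 and 8.09. Tag ratios were 2.87 (2.36 to 3.51), 3.04 (1.99 to 4.75) and 5.68 (3.10 to 11.2). The next NKT-only peaks had little control signal: chr2:172909264-172909598 had a density of 41.5 with 65 ChIP tags and no control tag, and chr12:26742642-26742872 had 29.5 with 41 ChIP tags and 1 control tag. The other shared peaks of the 10 were chr19:8786383-8786800 at 36.0 and chr7:107755605-107755977 at 32.7, next to the positions on chromosomes 1, 12 and 17 named above.

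The 2 lists also differed in strand shift, a deposited value for the offset between the tags of the forward and reverse strand. In a bound region this offset depends on fragment length. Whether the value is the whole offset or a part of it was not given in the sources used here. The median shift was 86 bp (quartiles 78 and 95) in injected thymocytes and 45 bp (37 and 58) in NKT cells. In the NKT list, shared peaks had a median shift of 70 bp (bootstrap 95% interval 69 to 72) and NKT-only peaks 42 bp (42 to 43). In injected thymocytes, shared and list-only peaks had medians of 87 and 86 bp. At the same 354 positions the NKT shift was the shorter one in 277 pairs, by a median of 16 bp over all pairs. Of the 475 NKT peaks with a shift of 60 bp or more, 53.7% (49.1% to 58.2%) were shared, against 6.51% (5.32% to 7.87%) of the 1521 with a shorter shift. The share did not rise throughout: it was 69.0% at 80 to under 90 bp and 24.7% (15.6% to 35.8%) of the 77 peaks at 100 bp or more. In injected thymocytes the corresponding shares were 8.29% of 4054 peaks and 11.7% of 162. Restricting both lists to peaks with a shift of 60 bp or more left 245 shared peaks, or 51.6% of those NKT peaks and 6.04% of those injected-thymocyte peaks.

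**Figure D3:**
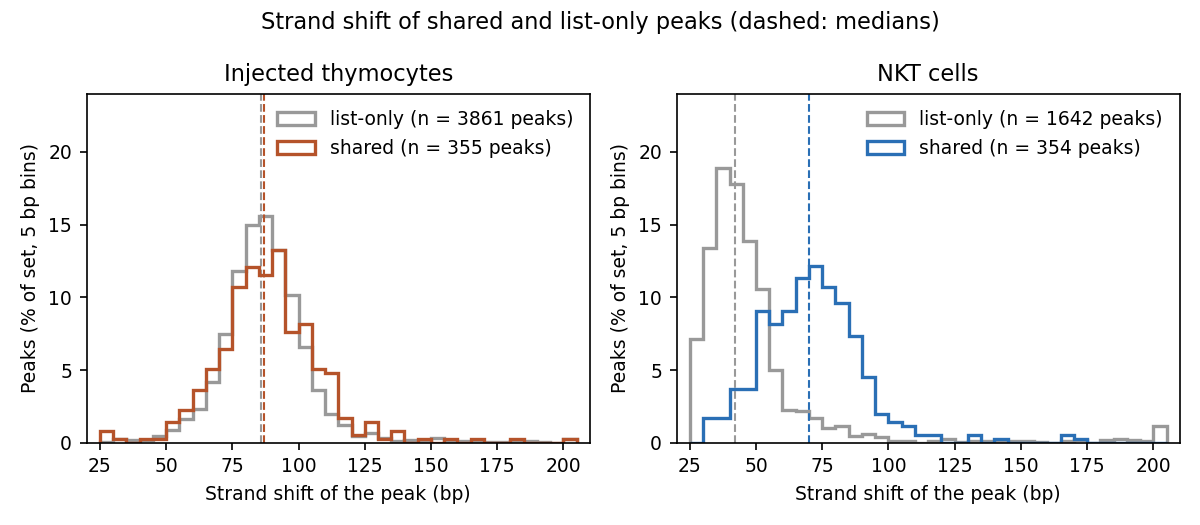
Distribution of the strand shift of peaks, in bp, as percent of each set in 5 bp bins, for shared (coloured) and list-only (grey) peaks of injected thymocytes (left) and NKT cells (right). Dashed lines are medians, at 87 and 86 bp on the left and at 70 and 42 bp on the right.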

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

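The control column of the peak lists was not used to match positions between the lists, although the lower limit of the fold, near 2.50, rests on it. At a few positions it held signal as high as a peak itself. The control density reached the lowest ChIP density of the list at 2 injected-thymocyte peaks and at 3 NKT peaks. The injected-thymocyte peaks were chr11:3030672-3038880 and chr5:147072452-147073008, neither of which was shared. The NKT peaks were chr6:124834746-124837706, which was shared, and chr11:3003335-3004809 and chr12:48934855-48935126, which were not. The tallest NKT peak had fewer ChIP than control tags (ratio 0.768 after scaling). A control density of 5 or more occurred at 21 injected-thymocyte and 18 NKT peaks, of which 2 and 12 were among the 100 tallest of their list.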

How the results depend on the processing

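The counts of shared peaks, 354 of NKT cells and 355 of injected thymocytes, stayed within 1.5 times under all planned criteria: 295 with a reciprocal overlap of 50%, 326 with summits within 100 bp, 372 and 379 with regions extended by 500 bp, 286 in the upper 50% of each list and 334 with equal numbers. Of the alternatives added after seeing the data, a control density under 3 gave 330 and a strand shift of 60 bp or more gave 245. This holds for the counts, whereas several shares moved out of their intervals. In injected thymocytes the share of 8.42% became 7.00% with a reciprocal overlap of 50%, 13.6% in the upper 50%, 16.7% with equal numbers and 6.04% with a shift of 60 bp or more. In NKT cells 17.7% became 14.8%, 28.7%, 16.7% and 51.6%, of which only the value with equal numbers stayed within the interval. In all, 40 of 62 alternatives stayed close to the value reported and 22 moved. Stricter densities shortened the lists by construction, to 2108 and 998 peaks in the upper 50% and 421 and 199 in the upper 10%, for injected thymocytes and NKT cells. Ranking by ChIP tags in place of density raised the shared part of the top NKT quartile from 48.5% to 58.9% and lowered that of the lower NKT quartiles from 7.48% to 4.01%. In the lower quartiles of injected thymocytes 1.30% became 0.886% by tags and 2.02% by fold; the cause was not tested. The shared part of the top 500 was 72.0% for the top 100 and 31% for the top 1000 in injected thymocytes, and 74.0% and 29.7% in NKT cells. The part shared between the top lists themselves went from 35.8% to 28.0% and 26.8%. Among injected-thymocyte peaks with a shift of 60 bp or more, 37.8% of the top 500 were shared, since fewer NKT peaks were left to match. Too few NKT peaks have such a shift for a top 500 of their own. Placement relative to transcription starts, genomic location, the EGR motif, genes with a peak and the gene lists were not run, since no mm9 annotation was used here. A median region rests on 16 or 15 ChIP tags, and the effect of depth was not tested.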

Other observations

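The tests against raised control signal, within density quartiles, of nearby peaks and of the density limit were set out before their results were seen; the widest regions and the chromosome counts were chosen after. Among regions with a control density under 1, the widest of the NKT list stood apart from the rest. It was chr9:48643773-48644749, 977 bp wide, against 518 bp for the next. It held 187 ChIP tags against 9 control tags, a ratio of 23.6 after scaling (12.2 to 52.4; the deposited tag enrichment is 16.6), with a density of 28.1 and a strand shift of 104 bp. The nearest listed injected-thymocyte summit was 417 kb away, whereas each of the 4 next widest NKT regions was shared. Besides this region, the 3 tallest of the NKT-only peaks with a shift of 60 bp or more and a control density under 3 were chr16:8306557-8306890 with a density of 29.4, chr6:87452988-87453312 with 24.8 and chr12:40949660-40949990 with 22.8. The widest such region of injected thymocytes, chr15:36538721-36539443, was 723 bp wide with 77 ChIP tags and no control tag, and was not shared.

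Chromosomes held similar parts of both lists, with chromosome 18 the farthest apart among 20 by the ratio of NKT to injected-thymocyte peaks. It held 4.21% of NKT peaks (3.37% to 5.18%) and 2.82% of injected-thymocyte peaks (2.34% to 3.37%), but 2.95% of NKT peaks with a shift of 60 bp or more. The X chromosome held 2.51% (1.86% to 3.29%) and 3.61% (3.06% to 4.21%). Of injected-thymocyte peaks found in that list only, 6.89% of the top density quartile had an NKT peak within 10 kb, against at most 3.65% in 1000 random placements. In the following quartiles it was 2.81%, 2.59% and 3.35%, against at most 3.19%, 3.07% and 2.87%, so that only the first and the last were above all placements.

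NKT-only peaks had a shorter strand shift than shared NKT peaks, by 28 bp (bootstrap 95% interval 26 to 29), which bears on whether they can be read as Egr2 binding specific to NKT cells. Fragment length in the NKT library was tried as an explanation in 2 forms, both set after the shifts were seen; both only restated this difference, so they were dropped and it stays untested. Peaks of low density having short shifts whether shared or not is argued against by the quartiles of density. In each of them the difference was 19 bp or more (12.5 to 34 in the weakest quartile). Tag count and width were not matched. Shared NKT peaks had medians of 26 ChIP tags and 261 bp, and NKT-only peaks of 14 ChIP tags and 133 bp. Few tags or a narrow region were therefore not tested as a cause. Raised control signal is argued against as the whole cause, since a difference of 26 bp (23 to 28) remained among peaks with a control density of at most 0.5. A hypothesis that stays open is that many short-shift NKT-only peaks may be tag clusters that arise without binding, and a form of binding in NKT cells with another tag profile was not tested.

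The positions of NKT-only peaks relative to injected-thymocyte peaks were used as a check on that hypothesis, under the assumption, not tested, that background would lie at random. Of 220 NKT-only peaks with a shift of 60 bp or more, 8.18% (4.92% to 12.6%) had an injected-thymocyte peak within 10 kb. This was above the highest of 1000 random placements (6.82%, mean 3.17%). It argues against positions that are uniformly random and independent of each other for this set. Of 1422 with a shorter shift, 4.57% (3.55% to 5.79%) did, and 2 of 1000 placements were as high (mean 3.19%, highest 4.85%). The shares differed by Fisher's exact test over peaks (two-sided p = 0.031). This test was not among those set out beforehand, and the 60 bp cut was chosen after the data were seen. Peaks are not replicates and some lie close together, so the p-value does not establish a difference between the sets. For the short-shift peaks a mixture of background and binding may hold and cannot be told apart from a preference of background tags for the same neighbourhoods.

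Peaks of the lower quartiles of the injected-thymocyte list were rarely shared (1.30%), and the lower density limit of the NKT list is a candidate explanation. Of the 61 injected-thymocyte peaks with a density of 40 or more, 45 were shared, and a ratio of NKT to injected-thymocyte density was taken for each, with 0 entered for those not shared. NKT regions absent from the list, among them those before number 44, could give no ratio. An injected-thymocyte peak at such a position counted as not shared, which can lower the expected share. If the ratios of all 61 held for weaker peaks, the limit of 9.96 would leave 0.129% shared (bootstrap interval 0% to 0.387%), which is less than observed. The bound set beforehand counted any departure from that interval against the limit, which was wrong, because a share above it is no lack of sharing. Peaks of the lower quartiles reach at most a density of 12.99, so only the highest of the 61 ratios could bring one above the limit. The expected share thus rests on few ratios, and whether the ratios of the tallest peaks carry over is not settled. Weaker binding in NKT cells under the limit and absence of binding cannot be told apart for these peaks.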
